A study of Arabidopsis thaliana with 4 samples.

How the data were processed

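The 4 libraries, 2 per group, are polyA-selected GMUCT libraries of Arabidopsis thaliana read at 50 nt with strand kept, per the labels' protocols. Per the submitters' processing notes, cutadapt 1.4.2 and STAR 2.4.0 were used, with the TAIR10 genome. The authors deposited 1 table per library with a gene model and its co-translational RNA decay index, a linear ratio. The formula of the index, its read minimum, the gene annotation and the number of reads are not given in the sources used here. The unit was read from the values, which were positive, never 0, and often simple ratios such as 0.5 or 1.5. What an index above or below 1 stands for is therefore not stated, and values are given as they are. With the depth unknown, no interval for counting error was made. Reads without molecular identifiers are not independent molecules.

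Groups were taken from the labels, with the replicate numbers 1 and 2 given there. The mutant titles carry different numbers, and whether these stand for alleles or for replicates is not stated. The labels describe the plants as untreated while the wild-type titles carry CHX, and no text resolves this. Pairs of libraries of one group had identical values at 0.737% and 0.736% of shared loci, so none was a copy of another. Every table held 1 model per locus. Gene symbols came from a RefSeq table of assembly TAIR10.1, used only for names because the authors' build is TAIR10, and 23397 of 23498 loci were found there, 9743 with a symbol. No coordinates are printed for the same reason, and the planned relation of the index to coding length and GC content was not run.

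Indices were put on the log2 scale with no pseudocount, since no index was 0. Loci with a value in all 4 libraries (17049) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust fitting) for the difference abh1 minus Col-0_CHX, and for the level of each group against 0, with Benjamini-Hochberg adjusted p under 0.05. The design had no covariate. The shift of the libraries was tested by an exact two-sided permutation of the 4 library medians. Gene lists were tested against other genes with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Fry, which asks whether the genes of a list move one way on balance and makes no comparison with other genes, gave lower values in abh1 for all 9 lists, with an adjusted p from 0.00347 for microRNA targets to 0.146. Listing of loci was compared with Fisher's exact test and exact binomial intervals at the 95% level. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

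The lists were light harvesting and photosystem, cytosolic ribosomal proteins, translation factors, RNA decay and small RNA machinery, microRNA targets, conserved upstream open reading frame genes, floral organ identity and meristem, tapetum and pollen, abscisic acid signalling, histones, early stress response and organelle encoded loci. They, the tests, the alternatives and the rule for named genes were fixed before the data were examined. A ribosomal list member whose symbol in the name table is that of a receptor kinase was left out. A root list of 13 loci and a leaf defence list of 9 loci were added later. The rule named ABH1, CBP20 and XRN4 first. It then took up to 12 symbols with the largest difference in each direction past the threshold and with both libraries of one group on one side of the other, or the 6 with the smallest p where fewer than 5 passed. It also took the 5 highest and the 5 lowest levels of each group among loci past the level test, which left levels of Col-0_CHX only, and up to 4 members per list with the smallest p. Because 0 loci passed in the main test, the same rule was also applied to the loci without repeated values, a choice made after the results were seen. Members of lists that passed there are also named outside the rule.

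A value was called repeated when over 10 loci of the same library had exactly that value. Leaving out loci with a repeated value in any library was a setting fixed beforehand. The others fixed beforehand were leaving out each library, a replicate block, centring, quantile normalization, robust or trended fitting, loci in at least 1 library of each group, loci without a log2 value of exactly 0, loci outside the outer 1% of each tail, the mean in place of the median, the loci of each library alone, a threshold of 0.1, and the top 20% in place of the top 10%. With 1 library of a group left out, the lone library is assumed to vary like the other group. A variance per group, limits of 5 or 20 loci for repeated values, and pairs of these choices were added after the data were seen.

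The tests were tried on simulated data with the spread of these libraries. For the comparison of abh1 with Col-0_CHX over 17049 loci, 0 of 50 loci were recovered at each log2 change of 0.5, 1, 1.5 and 2. Over the 6572 loci without repeated values, 2, 42, 46 and 50 of 50 were recovered at those changes, with 8 false calls. Only these few loci were changed and no shift of whole libraries was set. The counts therefore do not give the recovery in data where many loci differ. Camera recovered a list of 40 genes shifted by 0.3 in both sets, and 1 of 100 random lists had p under 0.05 in each. The simulated genes varied independently, so this cannot show how camera behaves where the genes of a list are correlated. In the data the estimated correlation of the lists over all loci ranged from -0.053 to 0.14.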

Results

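Uncapped, polyadenylated RNA was sequenced from Arabidopsis thaliana in 4 libraries, 2 labelled as a loss-of-function mutant of ABH1 (the abh1 libraries) and 2 labelled Col-0_CHX, whose labels give the wild type. ABH1 is the large subunit of the nuclear complex that binds the cap of messenger RNA. The method, global mapping of uncapped and cleaved transcripts (GMUCT), reads the first base of RNAs that have lost their cap, which are mostly intermediates of decay or products of cleavage. Each library has 1 co-translational RNA decay index per gene, a ratio without a unit. The abbreviation CHX is not spelled out in the labels. All 4 libraries are labelled as immature inflorescence from plants about 4 weeks old, grown with 16 h light and 8 h dark. The comparison asks how the index differs between the 2 kinds of library, and cannot say what the lack of ABH1 does by itself. Genotype and the CHX of the title differ together here, and tissue or library batch may differ too. Nothing in the labels says whether the replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

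Genes of the flower differed between the groups in whether they had an index at all. All 18 loci of the list of floral organ identity and meristem genes had an index in both abh1 libraries, and 3 had one in both libraries labelled Col-0_CHX. AP1, AP3, PI, SEP2, SEP3, LFY and STK, transcription factors that set the identity of the flower or its organs, were among the 12 with an index in both abh1 libraries and in neither Col-0_CHX library. Of the 19 loci of the tapetum and pollen list, which serve the nurse tissue of the anther and the pollen coat, 19 had an index in both abh1 libraries and 2 in both Col-0_CHX libraries. By contrast, all 43 light harvesting and photosystem loci, all 32 histone loci and all 14 early stress response loci had an index in all 4 libraries.

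In the abh1 libraries the index was 1.23 and 1.21 for AP1, 1.14 and 1.13 for AP3, 1.09 and 1.07 for PI, and 0.962 and 0.915 for SEP3. Among the anther genes it was 1.03 and 1.03 for AMS, a regulator of the tapetum, and 1.27 and 1.28 for GRP17, a protein of the pollen coat. The 3 floral loci with an index in all 4 libraries were AP2, SEP4 and SPT. AG (2.5), SHP1 (1.5) and SEP1 (1) each had a value in 1 Col-0_CHX library only. Of all loci outside each list with an index in both abh1 libraries, 78.0% (floral) and 78.1% (tapetum and pollen) also had one in both Col-0_CHX libraries. Against these, the floral list (16.7%) and the tapetum and pollen list (10.5%) had lower shares by Fisher's exact test across loci, two-sided, with p = 5.51e-08 and p = 6.97e-10. Adjusted by Benjamini-Hochberg over 13 lists, these were 2.39e-07 and 4.53e-09.

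The other lists fixed beforehand had an index in both Col-0_CHX libraries at or above the share of loci outside them, which was 77.8% to 78.0%. The higher share did not pass Fisher's exact test for microRNA targets (85.2%, adjusted p = 0.240), early stress response genes (all 14, adjusted p = 0.0654) or genes with a conserved upstream open reading frame (81.2%). Of the lists added later, leaf defence (all 9) did not pass either, with an adjusted p of 0.240. The root list was lower, with 0 of the 4 loci listed in both abh1 libraries (adjusted p = 0.0038), but only 1 of these 4 had no value shared by over 10 loci of an abh1 library, and over such loci the adjusted p was 0.171. Under that filter, applied to every list after the results were seen, the floral list (adjusted p = 4.13e-08) and the tapetum and pollen list (adjusted p = 1.56e-11) stayed lower. Ribosomal proteins alone stayed higher past the threshold (95.7% against 89.7%, adjusted p = 0.0207), and the upstream open reading frame list turned, at 76.9% against 89.8% (adjusted p = 0.201). Of 61 microRNA targets, 61 had an index in both abh1 libraries and 52 in both Col-0_CHX libraries. For the 31 genes of RNA decay and small RNA pathways the numbers were 31 and 30, and for 33 translation factors 32 and 32. Of 201 cytosolic ribosomal protein loci, 199 and 188 had an index, of 37 abscisic acid signalling loci 34 and 35, and of 16 genes with a conserved upstream open reading frame 16 and 13. No locus of the chloroplast or mitochondrial genome had an index in any library.

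**Figure D1:**
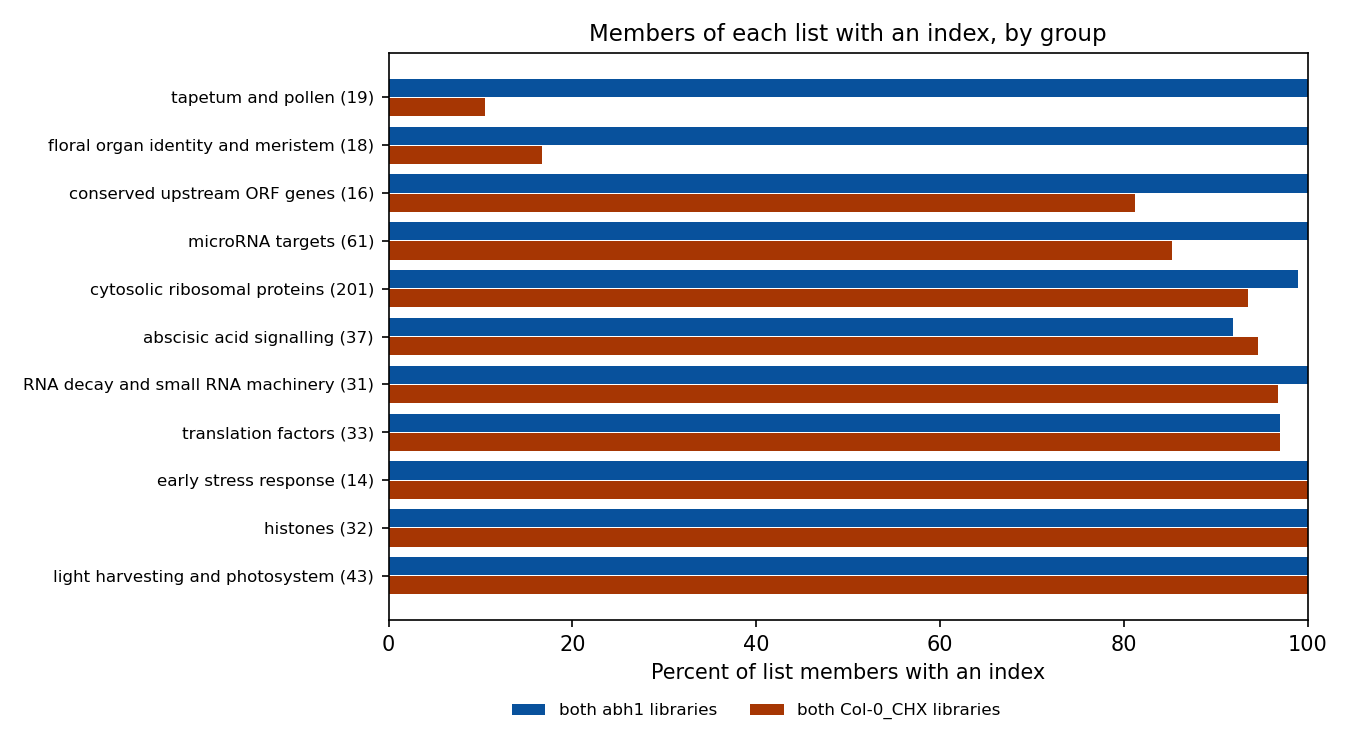
Bars give the percent of the members of each fixed gene list (number of members in brackets) that had a decay index in both abh1 libraries or in both Col-0_CHX libraries. Floral and pollen loci were complete in abh1 and reached 16.7% and 10.5% in Col-0_CHX, while light harvesting, histone and early stress loci were complete in both.

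The abh1 libraries held 22495 and 22492 loci and the Col-0_CHX libraries 18321 and 18215, with 17049 in all 4. The number of reads behind each index was not among the values used here, so the depth is unknown and no counting interval can be given. A sign of low depth is that values repeat exactly between loci, as ratios of small whole numbers do. A value shared by over 10 loci of its library was held by 27.2% and 29.3% of the loci of the abh1 libraries, and by 43.6% and 42.7% of those of the Col-0_CHX libraries. Of the 17049 loci in all 4 libraries, 6572 had no such repeated value in any library.

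Most genes had a lower index in the abh1 libraries. The median index over the 17049 loci was 1.15 and 1.14 in abh1, against 1.37 and 1.29 in Col-0_CHX. On the log2 scale the library medians were 0.19 ± 0.0042 (SD, n = 2) in abh1 and 0.41 ± 0.058 (SD, n = 2) in Col-0_CHX, a difference of -0.22, or a 1.16-fold higher index in Col-0_CHX. Each abh1 library lay below each Col-0_CHX library, with differences of -0.18 to -0.26. An exact two-sided permutation test of the 4 medians gave p = 0.333, the smallest that 2 libraries against 2 allow. The index also spread more among genes in Col-0_CHX, with an SD across loci of 0.67 and 0.65 on the log2 scale against 0.40 and 0.40 in abh1.

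**Figure D2:**
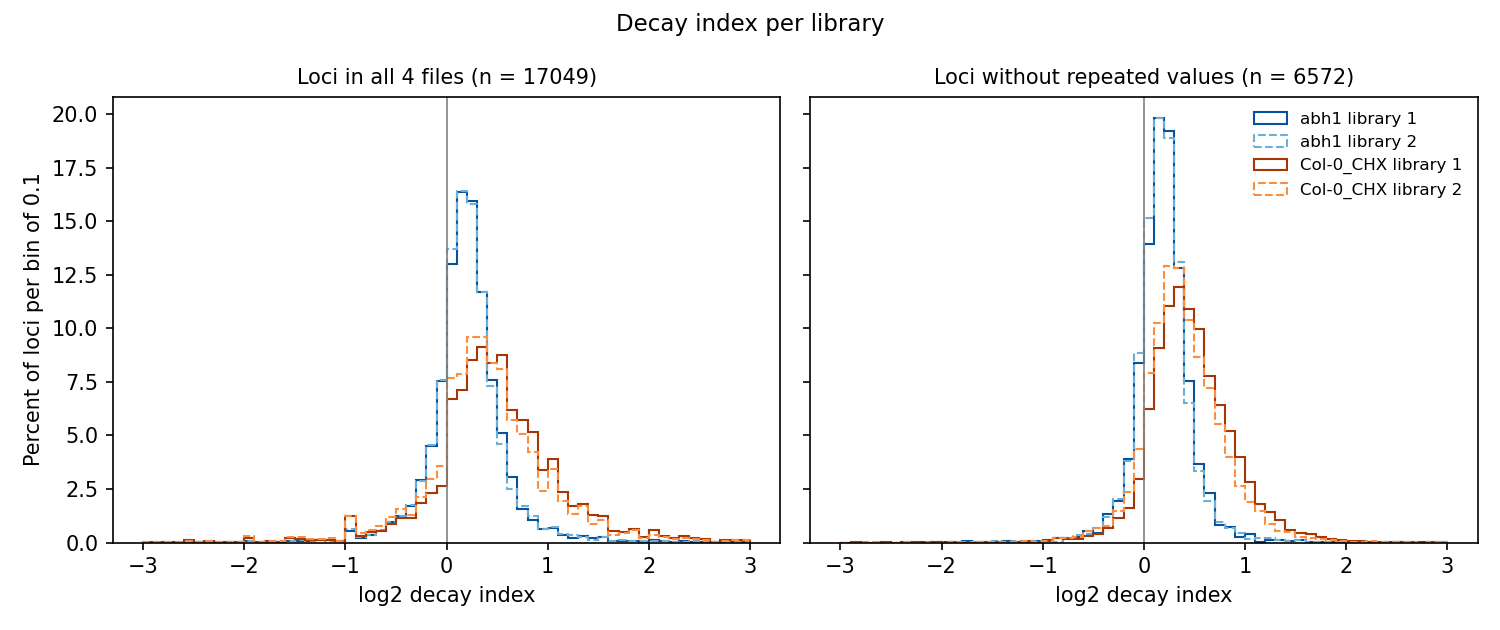
Histograms of the log2 decay index (x axis) as percent of loci per bin (y axis) in each of the 4 libraries, for the 17049 loci in all 4 libraries and for the 6572 without repeated values. The 2 abh1 curves lie over each other with medians near 0.19, and the 2 Col-0_CHX curves are wider and shifted to higher values.

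Gene by gene, ABH1 itself (AT2G13540) had an index of 1.01 and 1.19 in the abh1 libraries and of 1.86 and 1.62 in Col-0_CHX. The formula of the index is not given in the sources used here, so this value was not used to check the genotype. CBP20, the small subunit of the same complex, had 1.11 and 1.22 against 1.45 and 1.53. XRN4, the cytoplasmic exonuclease that degrades uncapped RNA from its front end, had 1.19 and 1.2 against 1.91 and 1.61. The log2 differences, abh1 minus Col-0_CHX, were -0.66 ± 0.17 (SE) for ABH1, -0.35 ± 0.14 (SE) for CBP20 and -0.55 ± 0.16 (SE) for XRN4. None of the 3 passed limma's moderated test, with Benjamini-Hochberg adjusted p of 0.198, 0.290 and 0.214.

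Across all 17049 loci, limma's test found 0 past an adjusted p of 0.05, and the smallest adjusted p was 0.167. At an unadjusted p under 0.05 there were 3422 loci, 2938 lower and 484 higher in abh1. With each library centred these were 1526 lower and 1087 higher, and with quantile normalization 1391 and 1256. Most of the imbalance thus went with the shift of the whole libraries. The 2 libraries of one group lay on one side of both libraries of the other at 56.0% of loci, with abh1 lower at 7713 and higher at 1828. For a single locus chance gives 33.3%. All loci share the same 4 libraries and the shift between them, so the excess is not evidence gene by gene. In simulated data with these 17049 loci and this spread, 0 of 50 loci changed by 2 on the log2 scale were recovered. That simulation changed few loci and set no shift of whole libraries, so recovery in the data may differ. With the 6572 loci free of repeated values, limma's test called 567 loci, 528 lower and 39 higher in abh1. That count was 0 when either abh1 library was left out, 1137 and 1957 without the first or the second Col-0_CHX library, 0 when a value shared by over 20 loci was the limit (smallest adjusted p 0.0607, 1318 under 0.1), and 0 after each library was centred on its median (smallest adjusted p 0.0665, 542 under 0.1). After centring all 567 still differed in the same direction, but this was fixed in advance. Centring took only the shift of -0.21 out of each difference, and a call needed a far larger one. Among called members of the lists the smallest was -0.61, for the ribosomal list member UBQ5.

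Among these 567, the genes with a symbol furthest below Col-0_CHX in abh1 were, by the fixed rule, MAP70-4, MIOX4, UBC34, SIB2, STP7, BEN1, HSF1, NIK1, RCAR1, HAM1, TCP2 and JAZ11. MAP70-4, a microtubule-associated protein, had an index of 1.18 and 0.999 in abh1 against 11 and 8.50, a log2 difference of -3.15 ± 0.18 (SE). MIOX4, a myo-inositol oxygenase, had 1.08 and 1.05 against 5.17 and 3.58. SIB2, which binds a plastid sigma factor, had 0.838 and 0.878 against 2.66 and 2.77, and the heat shock factor HSF1 had 0.951 and 1.00 against 2.73 and 2.85. The ubiquitin-conjugating enzyme UBC34 had 0.320 and 0.362 against 1.11 and 1.16. BEN1, which acts in brassinosteroid metabolism, had 0.230 and 0.240 against 0.707 and 0.638. NIK1, a receptor kinase, had 1.21 and 1.19 against 3.14 and 3.60, and JAZ11, a repressor of jasmonate signalling, 0.925 and 0.787 against 2.23 and 2.21. The limma adjusted p of each of these, over the 6572 loci, was 0.0383. Extreme ratios are rare, so values such as 11 and 8.50 can pass the filter on repeated values with few reads behind them. The depth is unknown and the rule ranks by size, so this limit weighs most on the first genes named.

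The genes with a symbol furthest above Col-0_CHX in abh1 were, by the same rule, FUM1, MRE11, THIC, ZAC, SCL13, TBL5, BETA-OHASE 1, FAB1D, MAP3KA, AGP25, mtLPD1 and RTM2. FUM1, the mitochondrial fumarase, had an index of 1.33 and 1.2 in abh1 against 0.176 and 0.203 in Col-0_CHX, a log2 difference of 2.74 ± 0.13 (SE) with a limma adjusted p of 0.0383. THIC, an enzyme of thiamine synthesis, had 2.95 and 4.14 against 1.48 and 1.41 (limma adjusted p = 0.0413). BETA-OHASE 1, a carotene hydroxylase, had 2.94 and 3.01 against 1.3 and 1.45. MAP3KA, a kinase of a mitogen-activated cascade, had 2.86 and 2.81 against 1.37 and 1.45. The mitochondrial lipoamide dehydrogenase mtLPD1 had 2.54 and 2.55 against 1.29 and 1.44. MRE11, a nuclease of DNA break repair, had 1.29 and 1.16 against 0.357 and 0.518. RTM2, which restricts the movement of a plant virus, was below 1 in all 4 libraries, at 0.697 and 0.714 against 0.394 and 0.363. Here too the lack of a repeated value does not show that many reads lie behind an index.

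Over all 17049 loci, the 6 symbols with the smallest p on the higher side were FUM1, ESP (AT4G22970), LRP1, AR192, CHR24 and ECT3, and on the lower side TCL1, MAP70-4, GH9B5, OFP12, DOT3 and SIB2. Each had a limma adjusted p of 0.167 and did not pass. ECT3, a reader of methylated adenosine in messenger RNA, had an index of 3.84 and 3.63 in abh1 against 1.11 and 0.804. TCL1, a repressor of leaf hair formation, had 1.01 and 0.954 against 4.25 and 4.00. Except for FUM1, MAP70-4 and SIB2, these had a repeated value in at least 1 library.

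**Figure D3:**
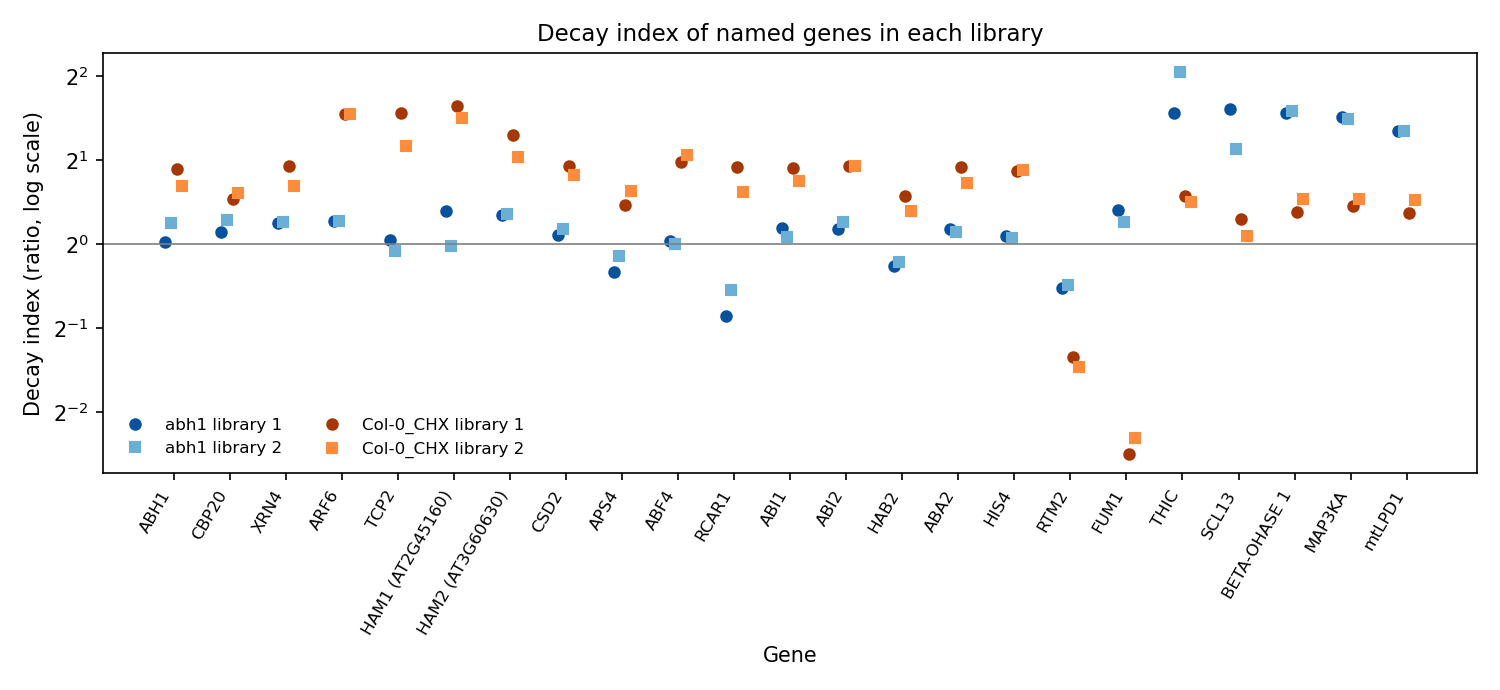
Points give the decay index (y axis, log scale, ratio) of 23 named genes in each of the 4 libraries, with a line at 1. The 6 microRNA targets and 6 abscisic acid genes shown lie higher in both Col-0_CHX libraries. FUM1, THIC, SCL13, BETA-OHASE 1, MAP3KA, mtLPD1 and RTM2 lie higher in both abh1 libraries. All of these were picked because they passed limma's test without repeated values, so their direction follows from the choice. In the full lists 13 of 52 microRNA targets and 9 of 34 abscisic acid loci were higher in abh1.

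Histone genes lay further below Col-0_CHX in abh1 than other genes did. In these libraries 3 of 18 floral and 2 of 19 tapetum and pollen loci had an index in both Col-0_CHX libraries, and all of them in both abh1 libraries. The median index of the 32 histone loci was 1.08 and 1.05 in the abh1 libraries against 1.45 and 1.33, a log2 difference of -0.43, which is -0.20 relative to all loci. Of the 32, 28 were lower and 4 higher in abh1, 0 passed over all loci and 5 were lower when adjusted over the list alone. The limma camera test against other genes, with a preset correlation of 0.01, gave an adjusted p of 0.0175 over 9 lists. With an estimated correlation the adjusted p was 0.699, and it ranged from 0.0148 to 0.791 over the alternatives tried. HTA11, a histone H2A variant, had 1.12 and 1.3 against 5.0 and 4.00. HIS4, a histone H4 gene, had 1.07 and 1.06 against 1.83 and 1.85. It was 1 of 4 histone loci past limma's test over the 6572 loci without repeated values. Histone genes have near-identical copies, so reads can be split among them and single loci are uncertain.

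Targets of microRNAs were lower in abh1 at 39 of 52 loci, and at 20 of the 21 without repeated values, where 72.2% of all 17049 loci and 77.0% of the 6572 without repeated values were lower. Their median index was 1.17 and 1.18 in abh1 against 1.5 and 1.52. Over all loci the list was -0.13 on the log2 scale relative to other genes, with a limma camera adjusted p of 0.426. Over the loci without repeated values it was -0.32, with a camera adjusted p of 0.0166 that became an adjusted p of 0.791 with an estimated correlation. Of all 6572 loci without repeated values, 528 fell in abh1 past limma's test. Among those 21 targets, 6 fell past it and 12 when adjusted over the list alone. The 6 were ARF6, TCP2, HAM1 (AT2G45160), HAM2 (AT3G60630), CSD2 and APS4. ARF6, an auxin response factor, had 1.21 and 1.21 in abh1 against 2.92 and 2.93, a log2 difference of -1.27 ± 0.095 (SE). TCP2, a regulator of leaf growth, had 1.04 and 0.944 against 2.95 and 2.24. HAM1 had 1.32 and 0.984 against 3.14 and 2.83. CSD2, the plastid copper and zinc superoxide dismutase, had 1.08 and 1.13 against 1.90 and 1.77. Without the second Col-0_CHX library the median of the full list relative to other genes was 0.012. Of the 18 floral loci, 3 had an index in both Col-0_CHX libraries compared here.

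Abscisic acid signalling genes did not stand apart as a list, with a median of -0.13 relative to all loci and a limma camera adjusted p of 0.317. Of its 34 loci, 25 were lower in abh1, where 72.2% of all loci were. An index in both Col-0_CHX libraries was given for 3 of 18 floral and 2 of 19 tapetum and pollen loci. Over its 22 loci without repeated values the camera adjusted p was 0.490, and 0.791 with an estimated correlation. Of all 6572 loci without repeated values, 528 fell in abh1 past limma's test and 1937 were lower at an unadjusted p under 0.05. Among the 22, 6 fell past the test over 6572 loci, and 10 when adjusted over the list alone. The 6 were ABF4, a transcription factor of the abscisic acid response, the receptor RCAR1, the phosphatases ABI1, ABI2 and HAB2, which hold the pathway off, and ABA2, an enzyme of abscisic acid synthesis. RCAR1 had 0.555 and 0.684 in abh1 against 1.89 and 1.54, a log2 difference of -1.47 ± 0.17 (SE). ABF4 had 1.03 and 1.00 against 1.97 and 2.08, and ABI1 had 1.14 and 1.06 against 1.87 and 1.69.

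Cytosolic ribosomal protein genes lay above other genes in the signed difference, but did not pass the main test. Their 188 loci had a median index of 1.14 and 1.13 in abh1 and of 1.22 and 1.18 in Col-0_CHX, a log2 difference of -0.074, or 0.15 relative to all loci. Of the 188, 113 were lower and 75 higher in abh1. The limma camera adjusted p was 0.0544 over all loci and 0.0166 without repeated values. With an estimated correlation the adjusted p was 0.699 and 0.791. The floral loci listed in both Col-0_CHX libraries numbered 3 of 18. RPL34 (1.1 and 1.04 against 2.32 and 1.95) and AT5G47700 (0.50 and 0.458 against 1.17 and 1.3) were among 3 that fell past limma's test over the 6572 loci, and AT3G14600 (1.25 and 1.14 against 0.519 and 0.605) was the 1 that rose. The 3 that fell and the 1 that rose became 2 and 1 when adjusted over the list alone. Ribosomal protein genes also have close copies that can share reads.

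The other lists did not pass. Light harvesting and photosystem genes had a median of 0.046 relative to all loci while camera placed them lower, so the median and the test differed in sign (adjusted p = 0.463), and after centring camera placed them higher (adjusted p = 0.226). Of the 43, 36 were lower in abh1. PSAD-2, a subunit of photosystem I, had 1.09 and 1.05 against 2.09 and 1.93 and was the 1 member past limma's test without repeated values. Translation factors had a median of 0.13 relative to all loci (limma camera adjusted p = 0.536), with 23 of 32 lower in abh1. The initiation factor eIFiso4G1 had 1.31 and 1.31 against 1.66 and 1.76. Genes of RNA decay and small RNA pathways had a median of -0.11 (camera adjusted p = 0.426), with 22 of 30 lower, PEL1 having 0.883 and 0.865 against 1.25 and 1.19. Early stress genes had 0.11 (camera adjusted p = 0.463), and genes with a conserved upstream open reading frame 0.024 (camera adjusted p = 0.426). In the last group GBF6, a bZIP factor whose upstream frame responds to sucrose, had 1.19 and 1.15 against 0.700 and 0.292. The floral list (3 loci) and the tapetum and pollen list (2 loci) had too few loci in all 4 libraries for the test.

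**Figure D4:**
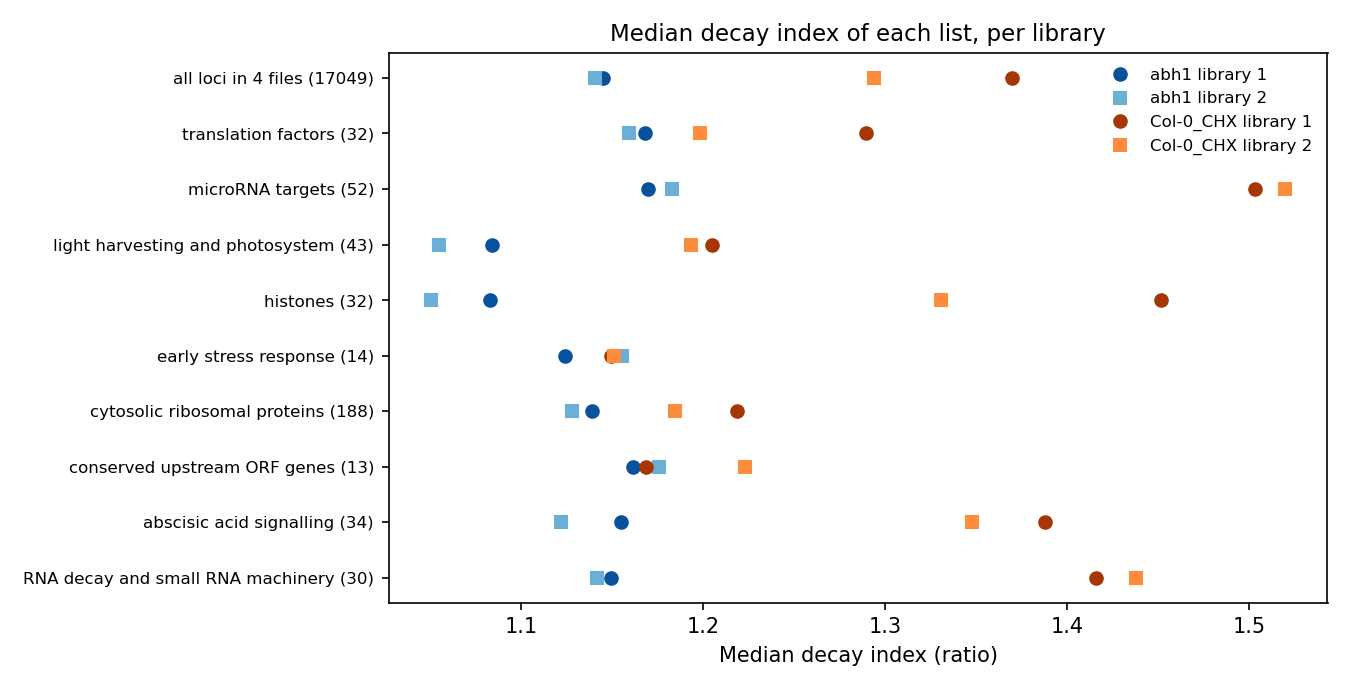
Points give the median decay index (x axis, ratio) of each fixed list with at least 10 loci, and of all 17049 loci, in each of the 4 libraries. MicroRNA targets reach 1.5 and 1.52 in Col-0_CHX and ribosomal protein genes 1.22 and 1.18, while every abh1 median lies between 1.05 and 1.18.

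The level of the index was also tested in each group against a log2 value of 0, an index of 1. In Col-0_CHX, 3909 loci lay above and 181 below by limma's test at an adjusted p of 0.05, and in abh1 0 lay above and 0 below. At an unadjusted p under 0.05 there were 2913 loci in abh1. The counts depended on how the spread was shared. With a variance for each group they were 665 above and 156 below in abh1 and 0 and 0 in Col-0_CHX, and without either abh1 library they were 0 and 0 in Col-0_CHX. Over the 6572 loci without repeated values and with a variance for each group, a setting chosen after the data were seen, 2714 lay above and 253 below in abh1, and 2683 above and 49 below in Col-0_CHX. The highest named levels in Col-0_CHX were those of MAP70-4, PKS4 (7.50 and 6.50), KMS2 (5.50 and 6.50), AR791 (10.5 and 3.17) and SWEET13 (5.75 and 5.75). The lowest were those of ATSYP24, FUM1, AR192, EMB3131 and GRXC2. GRXC2, a glutaredoxin, was low in every library, at 0.251 and 0.287 in abh1 and 0.286 and 0.273 in Col-0_CHX. Of these, MAP70-4, FUM1 and GRXC2 had no repeated value, which does not show that many reads lie behind them.

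Genes ranked more alike within a group than between groups. Across the 17049 loci, which are not independent replicates, Spearman's correlation was 0.445 between the abh1 libraries, 0.285 between the Col-0_CHX libraries and 0.114 to 0.123 between libraries of different groups. Over the 6572 loci without repeated values these were 0.634, 0.522 and 0.194 to 0.211. The top 10% of loci by index shared 708 loci between the abh1 libraries and 465 between the Col-0_CHX libraries, against 170.5 for independent lists. Libraries of different groups shared 255 to 275.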

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

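All tests of explanations here were chosen after the results were seen. Outside the 17049 loci compared, 3538 loci had an index in both abh1 libraries and in neither Col-0_CHX library, against 244 the other way round. This stood out because it is a signal in loci that the comparison of indices does not use. Of the 3538, 73.5% had a repeated value in an abh1 library, as against 26.5% of the loci in all 4 libraries.

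The floral and pollen loci are part of that set, and their loss from Col-0_CHX has more than one candidate explanation. Fewer reads in the Col-0_CHX libraries are argued against as the whole cause. Among loci without a repeated value in either abh1 library, 4 of 28 floral and pollen loci (14.3%, exact 95% interval 4.03 to 32.7) had an index in both Col-0_CHX libraries, against 90.0% of 13925 others (Fisher's exact test, p = 1.78e-20). Tissue made up largely of roots is argued against, since 0 of the 13 root loci were listed in both Col-0_CHX libraries. WOX5 had a value in the second of these libraries only, 0.5. Of the 5 root loci found in any library, 0 were listed in both Col-0_CHX libraries and 4 in both abh1 libraries. Only 1 of these 4 had no repeated value there. For a small share of root tissue this cannot decide, since few root loci were found in any library and the depth is unknown. Green shoot tissue without flower buds, the genotype and the CHX of the title cannot be told apart, since 0 libraries carry only 1 of these differences, and the label of immature inflorescence for Col-0_CHX may need a second look.

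The higher index of Col-0_CHX over most genes is the other pattern. Over the 6572 loci without repeated values the library medians of the groups differed by -0.21, against -0.22 over all loci. The smallest difference between a pair of libraries was -0.17 there, against -0.18 over all loci. Ratios shared by many loci are thus argued against as the whole cause. For ratios of few reads in general this cannot decide, since rare ones pass that filter and the depth is unknown. A difference in which loci were listed is argued against. The library medians of the groups differed by -0.220 over the loci in all 4 libraries, and by -0.215 with each library over its own loci. The genotype, the CHX of the title, the tissue and the library batch cannot be told apart, since 0 libraries carry only 1 of these differences.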

How the results depend on the processing

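The shift between libraries kept its direction under all 7 alternatives, from -0.18 to -0.26, and the exact p stayed at its smallest value. The count of loci past the threshold was 0 under every alternative that kept repeated values, with leave-one-out at 0 to 0. Without repeated values it was 567, and then 427 with a variance per group and 216 with the replicate block. It was 658 with a limit of 5 loci, 0 with a limit of 20, 0 with centring (675 higher and 975 lower at an unadjusted p under 0.05, against 203 and 1937 uncentred), and 0 to 1957 with 1 library left out. The values gave no sign that the replicate numbers pair the samples (correlation of deviations -0.0043 over all loci and 0.011 without repeated values). With 2 libraries per group this cannot settle how they were prepared. The block gave 0 calls over all loci, as did the main fit. For histones the median relative to other genes was -0.20 to -0.12 without single libraries, past the threshold only without the first abh1 library; it was -0.20 with an estimated correlation, -0.15 without repeated values and -0.15 with both, none past it. Ribosomal protein genes passed with the replicate block (0.15), centring (0.15), quantile normalization (0.12) and without repeated values (0.13), and microRNA targets without repeated values (-0.32). With an estimated correlation neither list passed (adjusted p 0.699 over all loci and 0.791 without repeated values for each). Camera turned its direction for light harvesting with centring (0.046) and for translation factors without the second Col-0_CHX library (0.084, in a range of 0.084 to 0.14 without single libraries and of 0.084 to 0.15 over all alternatives). Loci above 0 in abh1 were 323 without repeated values and 665 with a variance per group, those below 64 and 156, and with both choices together 2714 above and 253 below. In Col-0_CHX those above were 0 to 5689 without single libraries, 0 with a variance per group and 7308 at the threshold of 0.1, those below 0 to 484, 0 and 360, and 91 without repeated values. With both choices together 2683 lay above and 49 below there. With the top 20% in place of 10%, the fold overlap over independent lists was 2.4, 2.01 and 1.33 (abh1, Col-0_CHX, different groups) against 4.15, 2.73 and 1.57. Single genes that turned direction were GRXC2 (0.037 without the first and -0.16 without the second abh1 library, with and without repeated values, 0.16 and 0.15 centred), AP2 (0.10 quantile), SPT (-0.75 without the first and 0.39 without the second Col-0_CHX library, 0.041 centred, 0.011 quantile) and eIFiso4G1 (0.015 quantile). The cause was not tested for any of these. Transcript averaging was not run, as each locus had 1 model. Unknown depth limits every single index.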

Other observations

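The test of an explanation in this part was chosen after the result was seen, as were the genes named here and the root and leaf defence lists. In all, 936 loci without a repeated value had an index in both abh1 libraries and in neither Col-0_CHX library, members of the floral and pollen lists among them. Outside those lists they include WUS, which maintains the stem cells of the shoot, DMC1, the recombinase of meiosis, and ANX1 and VGD1, which act in the pollen tube. In the other direction 51 such loci had an index in both Col-0_CHX libraries only. They include FMO1, an enzyme of systemic defence, YUC5 and YUC9, enzymes of auxin synthesis, IDA, a peptide of organ shedding, the transcription factors WRKY55 and WRKY62, and IAA29, a repressor of the auxin response. All 9 loci of the leaf defence list, such as PR1 (1.4 and 1.66 in abh1, 1.36 and 1.77 in Col-0_CHX), had an index in all 4 libraries. Of the 13 root loci, 4 had one in both abh1 libraries and 0 in both Col-0_CHX libraries.

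MicroRNA targets may stand apart because a target's index can be set by its 1 dominant cleavage position. The size of the log2 index of the 21 targets without repeated values, whatever its sign, had a median of 0.28 in abh1, at percentile 93.7 of 10000 random lists of that size. In Col-0_CHX it was 0.82, above all of them. The high level of the targets in Col-0_CHX is part of the pattern itself, so that percentile is not a separate test. The explanation needed both groups above percentile 95, and abh1 did not reach it, so this does not decide. The genotype, the CHX of the title and the tissue also cannot be told apart here, as 0 libraries carry only 1 of these differences.

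Over the 6572 loci without repeated values, Pearson's correlation across loci was 0.756 within abh1, 0.547 within Col-0_CHX and 0.268 on average between groups (95% bootstrap interval over loci 0.229 to 0.310). The geometric mean of the within-group values was 0.643, the value expected between groups if libraries differed only by their own independent noise. Libraries within a group may also share a batch, tissue or preparation that raises their correlation, so the cause of the gap cannot be told. The interval resamples loci as if independent and does not measure the spread between libraries. Among 48 gene families grouped by their symbols, 0 passed limma's camera test, the smallest adjusted p being 0.597 for the NUDT family (16 loci, 0.28 relative to all loci, unadjusted p = 0.0306). At an unadjusted p under 0.05 it was the 1 family.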
